A study of Mus musculus with 8 samples.

How the data were processed

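RNA was measured in cultured mouse T cells of the pathogenic TH17 type, an IL17-producing helper T cell state associated with autoimmune inflammation. Per the labels' protocols, naive CD4 T cells from spleen and peripheral lymph nodes of wild-type C57BL/6 mice, above 98% pure, were stimulated on plates coated with anti-CD3 (1 µg/ml) and anti-CD28 (3 µg/ml). The medium held IL6, IL1β and IL23 at 20 ng/ml each and blocking antibodies against interferon gamma and IL4 at 10 µg/ml each. The treated cells received NorUDCA at 500 µM for 4 h. NorUDCA is norursodeoxycholic acid, a homologue of the bile acid ursodeoxycholic acid with a shorter side chain. The untreated cells are described as having no treatment, and no vehicle is named in the labels. Libraries were made from about 250 ng of total RNA with a NEBNext kit, per the labels' protocols.

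The authors deposited a table of raw counts per gene and a table of FPKM values for the same 8 libraries. STAR 2.7.11b, Picard 2.19.2, DESeq2 1.40.2 and R 4.3.3 are named, without their roles, per the submitters' processing notes, and so is the mouse genome build GRCm39 (mm39). The counting program and whether it used the strand of the reads are not given in the sources used here. Reads of genes that overlap on the genome, or of near-identical copies, therefore may not be separated, and overlaps are named beside the tested genes that the rule below selected. The count table has a row for each of 57186 genes and 92 spike-in sequences, and the spike-in rows hold 0 counts in all 8 libraries and were left out. The deposited FPKM values were derived from the same counts: over 10317 genes with at least 100 counts, they equalled the count divided by a constant per gene and by the median-of-ratios size factor of the library, with a largest relative deviation of 6.66e-16. FPKM therefore served only for alternatives. Gene symbols, identifiers and coordinates are those of the count table, on GRCm39; the mouse reference sequence at hand was of another build and was not used.

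Libraries were grouped by the labels as 4 untreated (control) and 4 NorUDCA libraries. Total counts ranged from 22127420 to 24306893 per library, so that 3 counts corresponded to between 0.123 and 0.136 CPM (the usual unit of counts scaled by library size); this floor covers counting error only. No 2 libraries of a group held the same values: chi-square per degree of freedom between replicate counts, over genes with at least 20 counts in the pair, ran from 1.65 to 3.26 among control and from 2.71 to 10.8 among NorUDCA libraries. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical.

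Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, filterByExpr with the group, and treatment as the only term. Adjusted p-values are Benjamini-Hochberg values over all 15143 genes tested, with a threshold of 0.05; a change of at least 2-fold is an absolute log2 fold change of at least 1. CPM values use TMM-scaled library sizes and are given as mean ± SD over 4 libraries, and log2 fold changes are NorUDCA over control with a standard error (SE). The 35 gene lists were written before the data were examined; 30 of them had at least 5 tested members. These were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated for each list and with fry. Single values per library were compared with a two-sided exact permutation test over 70 assignments, whose smallest possible p is 0.0286. On simulated counts for the 15143 genes, 4 against 4, the edgeR test recovered 52% of 50 genes changed 1.2-fold and 80% of those changed 1.5-fold. It recovered 98% of those changed 2-fold and 100% of those changed 4-fold, and 2.72% of its calls were false. The simulation changed 200 genes by these factors, against 8896 called in the data, so its adjusted threshold was stricter. These shares therefore do not measure the power of the comparison made here.

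The rule for named genes was fixed before the data were examined. It took the 10 largest increases, the 10 largest decreases and the 5 smallest p-values in each direction among genes past the threshold with a mean of at least 5 CPM, a symbol that is not a predicted or clone name, and no overlap between the groups. It also took 26 genes fixed by name, and from each list up to 4 passing members with the largest change, or the 2 highest expressed where none passed. Other list members are named as examples within their list, and genes named outside the rule are said to be so. Alternatives were DESeq2 1.42.0, RLE, upper-quartile and library-total scaling, 2 other low-count filters, limma-voom, a robust fit, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, blocks for replicate number and library-number range, each range alone, removal of mitochondrial or ribosomal RNA genes, an FDR of 0.01 and leaving out each library in turn. The removal of ribosomal RNA genes, the counts with a mean of at least 5 CPM, the fit without NorUDCA libraries 1 and 3, and 4 further gene lists were added after the data were seen. Some genes that the rule for named genes or a list selects are not reported here, although list counts and set tests include them.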

Results

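The effect of NorUDCA on the transcriptome of cultured pathogenic TH17 cells was examined by RNA sequencing of 4 libraries from cells without it (control; no vehicle is named for them) and 4 from cells exposed to 500 µM NorUDCA for 4 h. The libraries held between 22127420 and 24306893 counts, with means of 23682100 ± 614886 in control and 22808900 ± 607839 in NorUDCA libraries (SD, n = 4 each; two-sided exact permutation p = 0.171). The first principal component held 68.3% of the variance and separated the 2 groups. The second held 7.54% and spread the NorUDCA libraries, with scores of -11.7 in library 1, -9.88 in library 4, 5.07 in library 2 and 20.0 in library 3.

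Transcripts for glucose uptake, glycolysis and the hypoxia response were lower in NorUDCA-treated cells, and so were those for ribosome production. Transcripts of the ATF4 stress program were higher, as was Cyp1a1, the cytochrome P450 gene classically induced through the aryl hydrocarbon receptor. With an estimated inter-gene correlation the glycolysis and hypoxia lists passed (adjusted p = 0.00725 each), but the ribosome biogenesis and ATF4 lists did not (0.352 and 0.523). Transcripts of the TH17 cytokines Il17a and Il17f did not pass the test for a difference. Of 15143 genes tested, 8896 (58.7%) passed the edgeR threshold, 4463 higher and 4433 lower with NorUDCA. Of these, 6575 changed by less than 1.5-fold. At least 2-fold changes were found for 747 genes, 522 higher and 225 lower; among the 10551 genes with a mean of at least 5 CPM, a limit added for this count after the data were seen, they were found for 140 higher and 94 lower genes. With scaling to library totals in place of TMM, 63.5% of the called genes were higher, against 50.2% with TMM. The library identifiers ran in 2 ranges, replicates 1 and 2 of both groups and then replicates 3 and 4; the first range alone called 7076 genes, the other alone 5573, and a fit with the range as a term 8775.

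**Figure D1:**
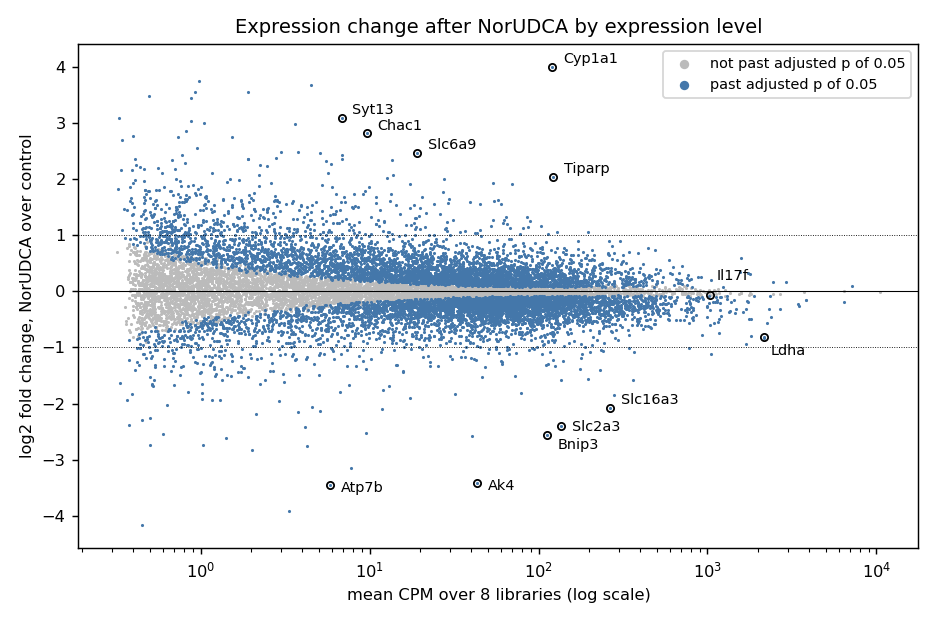
Log2 fold change of each tested gene (y axis, NorUDCA over control) against its mean CPM over 8 libraries (x axis, log scale); blue points passed the edgeR adjusted p of 0.05, dotted lines mark 2-fold changes, and circles mark some of the genes named in the text. Cyp1a1 lies highest among genes with at least 5 CPM at a log2 fold change of 4.00, and Atp7b lowest at -3.45.

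The largest increase among genes of at least 5 CPM was that of Cyp1a1 (ENSMUSG00000032315.7, chromosome 9, 57595211 to 57611107, plus strand), which rose 16.0-fold from 14.2 ± 2.30 to 227 ± 44.2 CPM (log2 fold change 4.00, SE 0.14, edgeR adjusted p = 1.43e-11). Ahrr, which encodes the repressor of the same receptor, rose 3.99-fold from 11.1 ± 0.766 to 44.1 ± 3.24 CPM. Syt13, a synaptotagmin gene, rose from 1.42 ± 0.389 to 12.2 ± 4.09 CPM, and Chac1 (chromosome 2, 119181710 to 119184862), which encodes a glutathione-degrading enzyme, from 2.40 ± 0.459 to 16.9 ± 3.27 CPM. The glycine transporter gene Slc6a9 rose 5.57-fold from 5.82 ± 1.24 to 32.4 ± 4.64 CPM. Its locus overlaps Ccdc24 and B4galt2, and Ccdc24 overlaps Gm17114 as well, so the 4.82-fold rise of Ccdc24 is uncertain. The other large increases were 5.52-fold for the stress gene Nupr1, 5.39-fold for Asb2, 5.13-fold for thrombospondin 1 (Thbs1, which overlaps Gm29233), 5.07-fold for Olfm2 and 4.99-fold for the urokinase receptor gene Plaur. With the smallest p-values, Rnf157 rose 2.23-fold, Smim3 3.76-fold and Mpp2 2.09-fold. The rule took only genes without overlap between the groups, so all of these were higher in each NorUDCA library than in any control library. Of all genes tested, 53.3% had no overlap between the groups.

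The largest decreases among genes of at least 5 CPM were those of Atp7b, a copper-transporting ATPase gene (chromosome 8, 22482801 to 22550321), and Ak4, a mitochondrial adenylate kinase gene (chromosome 4, 101276474 to 101324192). Atp7b fell from 10.7 ± 0.678 to 0.968 ± 0.253 CPM (log2 fold change -3.45, SE 0.13, edgeR adjusted p = 4.32e-11), and Ak4 was 10.7-fold lower, from 79.1 ± 3.06 to 7.39 ± 1.63 CPM (log2 fold change -3.42, SE 0.09, edgeR adjusted p = 1.54e-12). The Wnt receptor gene Fzd7 was 8.89-fold lower, at 1.56 ± 0.380 CPM with NorUDCA. Hilpda, whose protein sits on lipid droplets, was 3.75-fold lower. Spsb2 was 4.39-fold lower; it overlaps the glycolytic gene Tpi1, which was 2.18-fold lower, so the size of its change is uncertain. The other large decreases were genes of the glycolysis and hypoxia lists. All 10 were lower in each NorUDCA library than in any control library, as the rule required.

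Genes of glucose uptake and glycolysis fell together. Of 22 members tested, 19 fell and 2 rose (20 and 2 adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 4.20e-36; adjusted p = 0.00725 with an estimated correlation). The glucose transporter gene Slc2a3 (chromosome 6, 122704768 to 122778599) was 5.25-fold lower, from 229 ± 19.5 to 43.6 ± 4.20 CPM, and Slc2a1, which overlaps Gm12868, 2.65-fold lower. Pfkl, which encodes a phosphofructokinase, was 3.61-fold lower and Pfkfb3, whose product makes its activator, 3.50-fold lower. Hexokinase Hk2 fell from 246 ± 4.61 to 114 ± 8.77 CPM, lactate dehydrogenase Ldha from 2739 ± 72.8 to 1553 ± 59.0 CPM, and the lactate exporter gene Slc16a3, which overlaps Csnk1d, from 429 ± 13.0 to 101 ± 7.56 CPM. Pfkfb4 (log2 fold change 0.39, SE 0.10) and Eno2 (0.28, SE 0.09) rose; like the exceptions named for other lists, they were picked after their values were seen.

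Targets of the hypoxia-inducible factor HIF1A also fell: 15 of 18 tested members were lower and 0 higher (15 and 1 adjusted over the list alone), with a median log2 fold change of -0.99 (camera adjusted p = 2.49e-34; adjusted p = 0.00725 with an estimated correlation). Bnip3, a mitophagy gene that overlaps Gm45507, was 5.89-fold lower, at 32.5 ± 3.15 CPM with NorUDCA. Ankrd37, which overlaps Ufsp2 and Lrp2bp, was 5.73-fold lower, the collagen prolyl hydroxylase gene P4ha2 4.29-fold lower, and Egln3, which encodes a hydroxylase of HIF1A itself, 3.00-fold lower. The Hif1a transcript stood at a log2 fold change of 0.02 (SE 0.04, edgeR adjusted p = 0.772), with a 95% interval from -0.08 to 0.11.

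**Figure D2:**
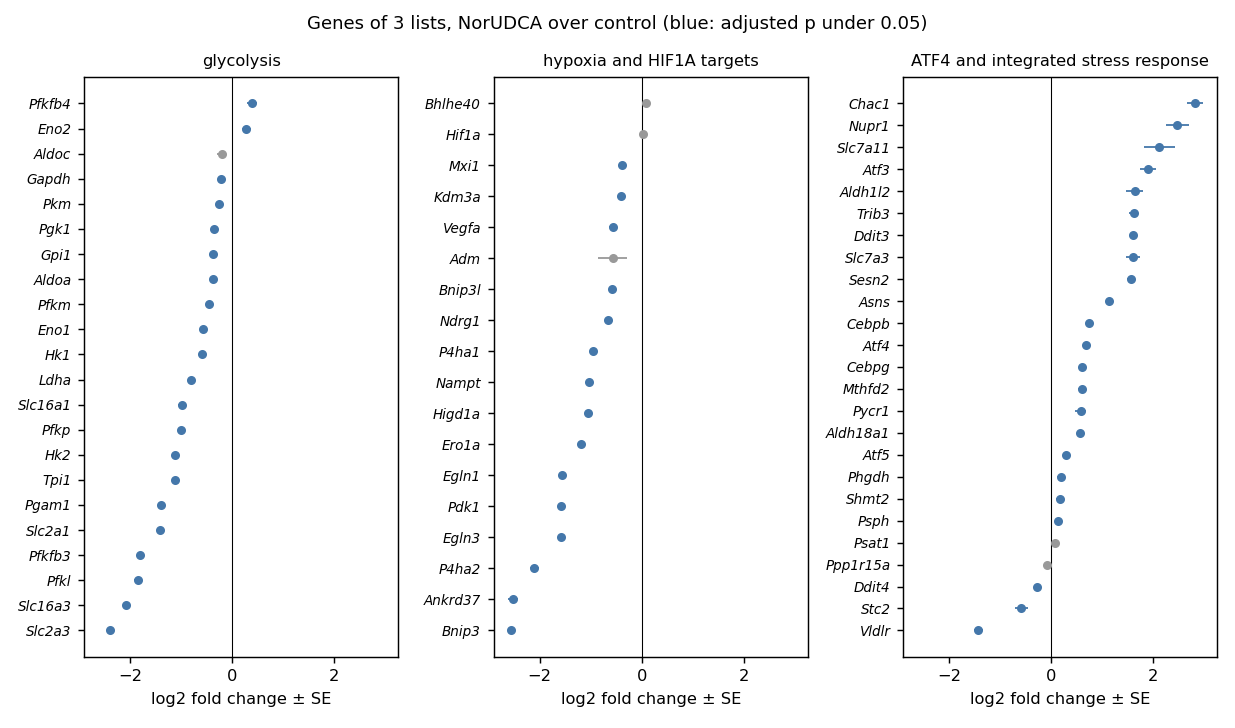
Log2 fold change (x axis, NorUDCA over control; bars are 1 SE) of each tested gene (y axis) in the glycolysis, hypoxia and ATF4 lists; blue points passed the edgeR adjusted p of 0.05. Of the glycolysis genes 19 of 22 and of the hypoxia genes 15 of 18 were lower, and 20 of 25 ATF4 genes were higher.

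Genes of the ATF4 and integrated stress response, a program that answers amino acid shortage and other stresses, mostly rose. Of 25 members, 20 were higher and 3 lower, with a median log2 fold change of 0.61 (camera adjusted p = 2.03e-09; adjusted p = 0.523 with an estimated correlation). Atf4 itself rose from 214 ± 7.41 to 342 ± 32.4 CPM, and Ddit3, which encodes the factor CHOP and overlaps Mars1, rose 3.03-fold from 19.4 ± 1.65 to 58.9 ± 4.32 CPM (edgeR adjusted p = 6.35e-11). The cystine transporter gene Slc7a11 rose 4.32-fold and Atf3 3.70-fold, from 0.432 ± 0.136 and 2.22 ± 0.298 CPM. Vldlr, Stc2 and Ddit4 fell, by 1.43, 0.59 and 0.28 on the log2 scale. Of 18 genes of the unfolded protein response of the endoplasmic reticulum, 11 were higher and 2 lower (15 and 1 with library totals), with a small median of 0.17 (camera adjusted p = 0.00389; adjusted p = 0.523 with an estimated correlation). Herpud1, Xbp1 and Edem1 rose by 0.86, 0.49 and 0.38, and Sdf2l1 and Hyou1 fell by 0.44 and 0.11, on the log2 scale.

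The list of glutamine transport and use split, with 7 of 17 members higher and 9 lower (camera adjusted p = 0.575). Gpt2, which encodes an alanine transaminase, rose 3.79-fold from 7.19 ± 1.44 to 27.3 ± 2.72 CPM. The glutamine transporter gene Slc1a5 fell by 0.61 on the log2 scale. Cad was 1.89-fold, Pfas 1.85-fold and Ppat, which overlaps Paics, 1.65-fold lower. With library totals 7 members were higher and 7 lower.

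Ribosome biogenesis genes fell almost without exception: 23 of 24 members were lower and 0 higher, with a median log2 fold change of -0.67 (camera adjusted p = 4.33e-23; adjusted p = 0.352 with an estimated correlation). Nolc1 was 2.08-fold, Nop16 2.04-fold, the RNA polymerase I subunit gene Polr1b 2.03-fold and Dkc1, which overlaps Mpp1, 1.96-fold lower. Myc, which encodes a factor that drives such genes, fell from 538 ± 11.9 to 380 ± 20.1 CPM (log2 fold change -0.50, SE 0.04, edgeR adjusted p = 3.75e-08). Of 26 cell cycle genes, 22 were lower and 0 higher, with a median of -0.28 (camera adjusted p = 0.000364; adjusted p = 0.716 with an estimated correlation). Among these, Ccne2, which overlaps Ints8, was 1.53-fold, Aurkb 1.51-fold, thymidylate synthase Tyms 1.46-fold and Pcna, which overlaps AV099323, 1.38-fold lower. With library totals 16 were lower and 1 higher. The proliferation marker Mki67 differed little, at a log2 fold change of -0.17 (SE 0.05, edgeR adjusted p = 0.0101), and did not pass with scaling to library totals (adjusted p = 0.176).

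Mitochondrially encoded messenger RNAs made up 1.55 ± 0.0534% of counts in control and 1.21 ± 0.0875% in NorUDCA libraries (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). Of 12 such transcripts tested, 11 were lower and 0 higher (12 and 0 adjusted over the list alone), with a median log2 fold change of -0.51 (camera adjusted p = 0.000105; adjusted p = 0.523 with an estimated correlation). mt-Nd1 fell from 2213 ± 53.5 to 1148 ± 101 CPM, mt-Cytb from 2757 ± 94.3 to 1545 ± 285 CPM, mt-Nd2 from 1166 ± 32.9 to 683 ± 49.0 CPM, and mt-Nd3 from 4.66 ± 0.641 to 2.49 ± 0.509 CPM. Of 37 nuclear genes of oxidative phosphorylation, 26 were lower and 0 higher (28 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.000705; adjusted p = 0.523 with an estimated correlation). With library totals 17 were lower and with upper-quartile scaling 20, with medians of -0.10 and -0.13. Cytochrome c (Cycs) fell by 0.44, Sdhd by 0.43, Uqcrfs1 by 0.37 and Ndufa4 by 0.37 on the log2 scale.

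Cholesterol synthesis genes were lower with NorUDCA. Of 24 members 19 fell and 0 rose, with a median log2 fold change of -0.38 (camera adjusted p = 0.000138; adjusted p = 0.686 with an estimated correlation). Isopentenyl diphosphate isomerase Idi1 was 1.75-fold, squalene epoxidase Sqle 1.66-fold, Lss, which overlaps 4930483K19Rik, 1.64-fold and the cholesterol carrier gene Stard4 1.57-fold lower. Of 14 fatty acid synthesis genes, 7 were lower and 2 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.0586). Leaving out control library 2, NorUDCA library 2 or NorUDCA library 3 brought this list past the threshold, at adjusted p = 0.0417, 0.0372 and 0.00754; so did the replicate block (0.0395) and leaving out NorUDCA libraries 1 and 3 (0.00661). Scd2 fell from 1458 ± 69.6 to 867 ± 115 CPM, fatty acid synthase Fasn from 849 ± 24.8 to 594 ± 61.0 CPM, and Acaca and Elovl6 fell by 0.41 and 0.36 on the log2 scale. Acsl3 and Mid1ip1 rose by 0.26 and 0.20.

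Targets of the sterol-sensing receptor LXR did not pass camera as a list, with 5 of 9 higher and 1 lower (camera adjusted p = 0.479, fry adjusted p = 0.0255). The cholesterol exporter gene Abca1 rose 1.91-fold from 9.44 ± 0.681 to 18.1 ± 2.43 CPM, Arl4c rose 1.41-fold, and Nr1h3, which encodes LXR alpha and overlaps Gm13783, rose from 0.490 ± 0.0538 to 1.16 ± 0.212 CPM. Apoe was 3.08-fold lower. Among bile acid receptors and transporters, 4 of 10 tested genes were higher and 2 lower (5 and 1 with library totals; camera adjusted p = 0.479). The glucocorticoid receptor gene Nr3c1 rose 1.42-fold, the sphingosine and bile acid receptor gene S1pr2 1.22-fold, and the exporter genes Abcc3 and Abcb1a, which overlaps Gm42686, 1.56-fold and 1.76-fold; Abcb1b and Abcc1 fell by 0.18 and 0.23 on the log2 scale. The vitamin D receptor gene Vdr stood at a log2 fold change of -0.08 (SE 0.10, edgeR adjusted p = 0.501). The bile acid receptor genes Gpbar1 (TGR5) and Nr1h4 (FXR) had at most 2 and 1 counts in any library, below the floor of 3 counts, and were not tested. Of 15 genes of fatty acid oxidation, 7 were higher and 2 lower (11 and 2 with library totals; camera adjusted p = 0.0586), and without NorUDCA library 3 the list passed at 0.0345, or without NorUDCA libraries 1 and 3 at 0.0484. Cpt1a, the entry enzyme of that pathway, rose 1.79-fold from 44.6 ± 0.601 to 79.9 ± 4.56 CPM, the lipid droplet gene Plin2 rose 1.44-fold, and Angptl4 and Acot1 fell by 0.53 and 0.95 on the log2 scale.

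Of the TH17 cytokine transcripts, those of Il17a and Il17f did not pass the test, while that of Il21 fell. Il17a (chromosome 1, 20801129 to 20804720) stood at 75.0 ± 5.99 CPM in control and 74.0 ± 6.23 CPM in NorUDCA libraries (log2 fold change -0.02, SE 0.06, edgeR adjusted p = 0.803). Il17f (chromosome 1, 20847370 to 20860841) stood at 1053 ± 14.2 and 1008 ± 66.2 CPM (log2 fold change -0.06, SE 0.04, edgeR adjusted p = 0.201). The receptor gene Il23r was 2.09-fold lower, from 8.27 ± 0.818 to 3.96 ± 0.842 CPM (log2 fold change -1.06, SE 0.13, edgeR adjusted p = 5.08e-06). The chemokine receptor gene Ccr6, which overlaps Gm33799, was 1.76-fold lower and the transcription factor gene Irf4 1.51-fold lower. Il22, Rora and Stat3 rose, by 0.83, 0.31 and 0.11 on the log2 scale. Over the TH17 lineage list, 4 of 17 genes were higher and 9 lower, with a median of -0.32 (camera adjusted p = 0.0251; adjusted p = 0.523 with an estimated correlation). This list call rested on NorUDCA library 3, without which the adjusted p was 0.0742.

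The signature of pathogenic TH17 cells had 8 of 14 genes higher and 2 lower. As a list it did not pass camera (camera adjusted p = 0.248), but it passed fry as higher (fry adjusted p = 0.000939). The chemokine gene Ccl4 rose 3.00-fold from 5.43 ± 0.371 to 16.3 ± 2.23 CPM (log2 fold change 1.58, SE 0.10, edgeR adjusted p = 7.90e-09), Il3 rose 2.89-fold, Ccl5 2.16-fold and Ccl3, which overlaps Gm53692, 2.09-fold. Csf2, which encodes GM-CSF and overlaps Gm12223, rose from 2.74 ± 0.206 to 4.22 ± 0.533 CPM, and Il22 from 0.892 ± 0.201 to 1.59 ± 0.152 CPM. The 2 lower genes were Il23r and Icos, which fell by 1.06 and 0.62 on the log2 scale. Weakly expressed genes rose as a class in these libraries: those with means above 10 and up to 50 counts summed to 3029 ± 41.2 CPM in control and 3335 ± 103 CPM in NorUDCA libraries (exact permutation p = 0.0286). Ccl4, Ccl3 and Csf2 lay above this range, with 117 to 426, 81 to 233 and 58 to 116 counts per library. Genes with means above 50 and up to 200 counts summed to 11076 ± 54.4 and 12029 ± 230 CPM. Those above 200 and up to 1000 summed to 98488 ± 299 and 99051 ± 283 CPM. These class sums rose by less than the genes named above, but a sum does not show the spread of single genes. Among genes with a mean under 5 CPM, 382 were at least 2-fold higher and 131 at least 2-fold lower. Whether the named genes stood apart from other weak genes was therefore not settled. The non-pathogenic TH17 signature split into 4 higher and 4 lower of 8 genes (camera adjusted p = 0.725). In it, Il10 rose 1.70-fold from 9.54 ± 0.860 to 16.2 ± 2.13 CPM, Il9 rose 1.58-fold (log2 fold change 0.66, but 0.42 without NorUDCA library 3), Il1rn 1.56-fold and Ikzf3 by 0.30 on the log2 scale. Ccl20, Ahr, Maf and Il6st fell by 0.56, 0.53, 0.32 and 0.32.

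**Figure D3:**
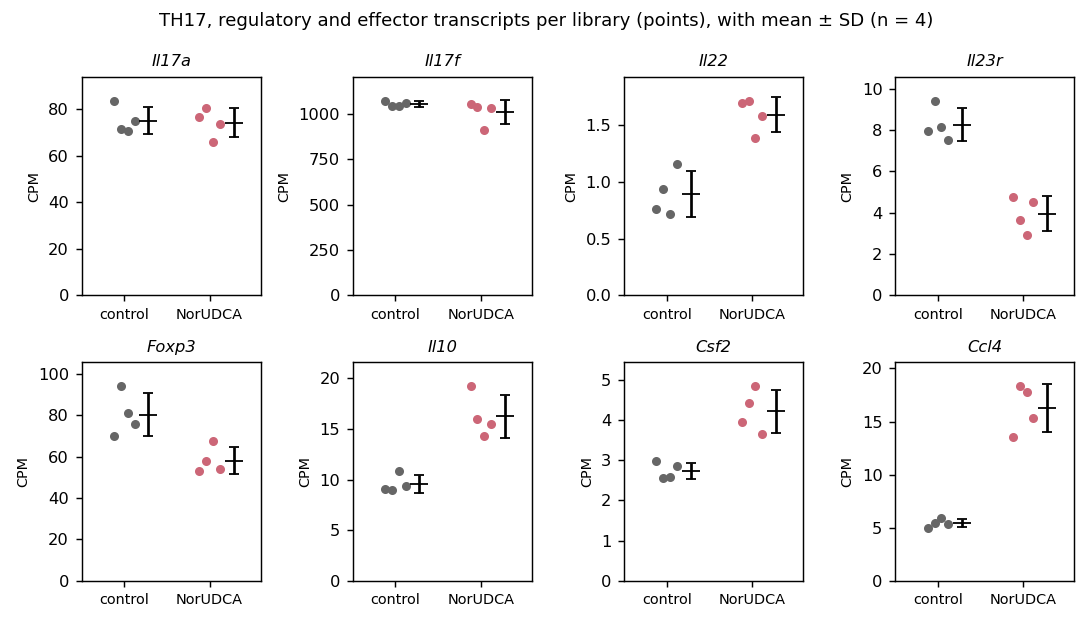
CPM (y axis, starting at 0) of 8 TH17, regulatory and effector transcripts in each library (points) of the control and NorUDCA groups, with mean ± SD (n = 4). Il17a and Il17f overlapped between groups, Il22, Il10, Csf2 and Ccl4 were higher in every NorUDCA library, and Il23r and Foxp3 were lower.

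Regulatory T cell genes also went both ways, with 8 of 20 higher and 8 lower (camera adjusted p = 0.645), or 11 and 8 with library totals. Foxp3, which encodes their lineage factor and overlaps Ppp1r3f, Flicr and Ccdc22, fell from 80.3 ± 10.4 to 58.1 ± 6.65 CPM (log2 fold change -0.47, SE 0.08, edgeR adjusted p = 0.000242). Lrrc32 was 2.15-fold, Gpr83 1.98-fold and Nrp1 1.88-fold lower. Of 10 TH1 genes, 3 were higher and 3 lower (camera adjusted p = 0.987). The TH1 factor gene Tbx21 stood at 1.83 ± 0.250 and 1.76 ± 0.603 CPM (edgeR adjusted p = 0.866), and Ifng, with 1 to 9 counts per library, was not tested. Il12rb1 rose by 0.20, and Il18rap and Cxcr3 fell by 0.36 and 0.23, on the log2 scale. Il12rb2, which overlaps Serbp1, passed at a log2 fold change of 0.23 (edgeR adjusted p = 0.0440), but not with DESeq2 (adjusted p = 0.168) or when any single library other than NorUDCA library 3 was left out (adjusted p = 0.0529 to 0.153). Of 4 TH2 genes tested, too few for a list test, Gata3 (which overlaps Gm13256) and Ccr8 rose 1.26-fold and 1.13-fold, and Ccr4 and Il4ra (which overlaps Gm44876) fell by 0.20 and 0.18. Without NorUDCA library 3, Il4ra stood at -0.11. Neither Il4ra with library-total scaling (adjusted p = 0.156) nor Ccr8 without control library 1 (0.0855), control library 4 (0.0723), NorUDCA library 1 (0.0630) or NorUDCA library 2 (0.0836) passed.

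Early response genes of T cell receptor signalling were mostly higher, with 16 of 24 up and 3 down (18 and 3 adjusted over the list alone) and a median log2 fold change of 0.29 (camera adjusted p = 0.000105; adjusted p = 0.523 with an estimated correlation). The nuclear receptor gene Nr4a2 rose 2.82-fold from 10.4 ± 0.546 to 29.3 ± 4.42 CPM, Fos 2.29-fold, and Nr4a3 and Fosb by 1.13 and 0.92 on the log2 scale. The 3 that fell were Myc, Ier3 and Junb, the latter 2 by 0.32 and 0.13. Interferon response genes were higher in 14 of 20 cases and lower in 3, with a median of 0.57 (camera adjusted p = 0.00174; adjusted p = 0.523 with an estimated correlation). Oasl1, Ifit1, Oasl2 and Ifit3 rose 6.73-fold, 5.61-fold, 5.13-fold and 3.50-fold from low levels, Ifit1 from 1.13 ± 0.261 to 6.37 ± 2.93 CPM. Weakly expressed genes as a class were also higher. Their summed level rose by less than these genes, but a sum does not show how far single weak genes moved. The more abundant guanylate-binding protein genes Gbp2, Gbp3 and Gbp7 fell by 0.54, 0.55 and 0.87 on the log2 scale.

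**Figure D4:**
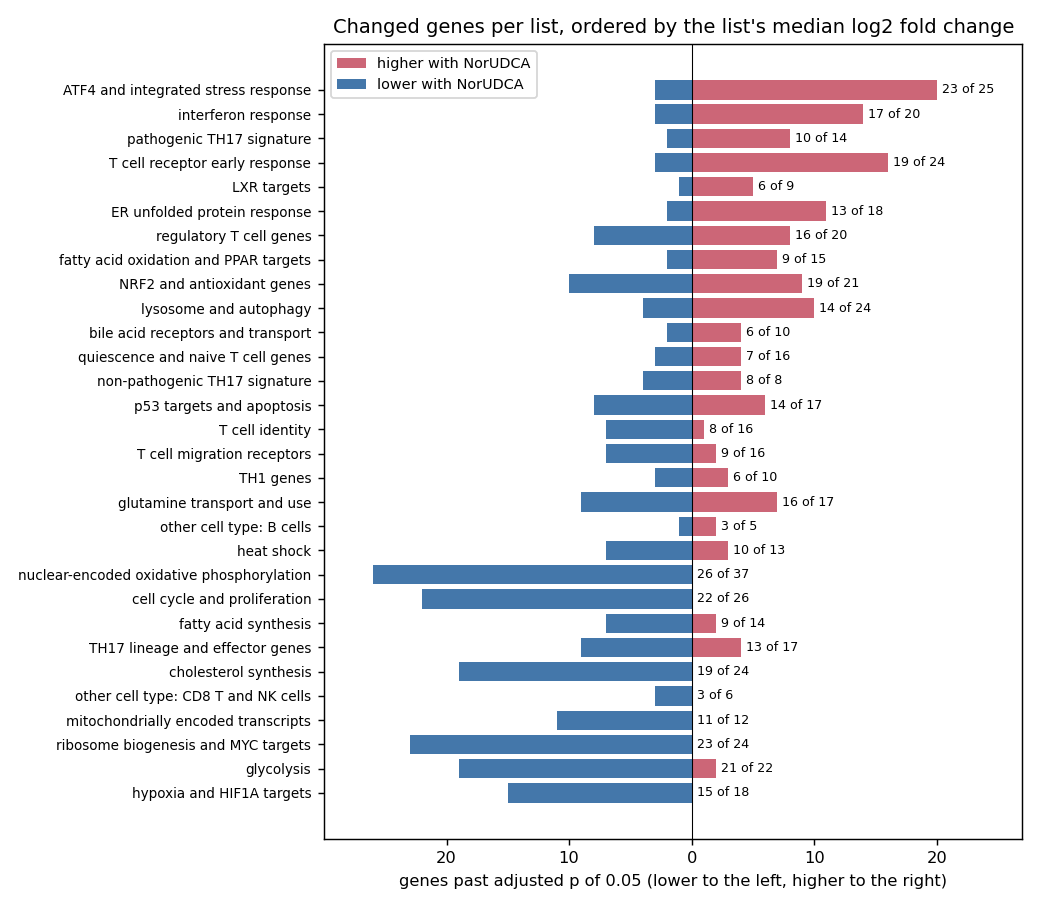
Number of genes past the edgeR adjusted p of 0.05 in each of 30 gene lists (y axis, ordered by median log2 fold change); bars to the right are genes higher and bars to the left genes lower with NorUDCA, and the text beside each bar gives the changed genes out of those tested. The hypoxia and glycolysis lists are at the bottom with 15 and 19 lower genes, and the ATF4 list is at the top with 20 higher genes.

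Several other lists changed in both directions and did not pass camera. By fry the T cell identity, heat shock, migration and NRF2 lists passed as lower (fry adjusted p = 0.00224, 0.00684, 0.0274 and 0.0341). The p53, lysosome and quiescence lists did not pass fry. NRF2 and antioxidant genes had 9 of 21 higher and 10 lower (10 and 10 adjusted over the list alone; camera adjusted p = 0.587), with Srxn1 up 3.35-fold and Nqo1 3.19-fold, and Pgd 1.69-fold lower. Heat shock genes had 3 of 13 higher and 7 lower (camera adjusted p = 0.473). Hspa1a, which overlaps Gm20481, rose from 0.293 ± 0.0648 to 3.53 ± 3.08 CPM and Hspa1b from 0.859 ± 0.235 to 4.07 ± 2.94 CPM, but these near-identical copies may share reads. NorUDCA library 1 held 8.02 and 8.19 CPM of them, against 1.32 to 3.07 and 1.51 to 4.02 CPM in the other NorUDCA libraries. Without it the log2 fold changes were 2.78 and 1.64, against 3.56 and 2.23 with it. Hspa4l rose 2.02-fold and the chaperonin gene Hspd1, which overlaps Hspe1, was 1.59-fold lower. Among p53 targets and apoptosis genes, 6 of 17 were higher and 8 lower (camera adjusted p = 0.725); Fas and Bbc3 rose 1.61-fold and 1.45-fold, and Aen and Bcl2 (which overlaps D630008O14Rik) were 1.79-fold and 1.63-fold lower. Lysosome and autophagy genes had 10 of 24 higher and 4 lower (camera adjusted p = 0.702), with Ctsl up 1.57-fold and Fnip2, Neu1, Gabarapl1 (which overlaps 1700101I11Rik) and Rragd, which fell by 1.05, 0.74, 0.58 and 0.39 on the log2 scale. Of 16 quiescence and naive T cell genes, 4 were higher and 3 lower (camera adjusted p = 0.587); Txnip (which overlaps Gm15441), Id3, Foxo1 (which overlaps Gm20402) and Btg1 rose by 0.60, 0.58, 0.42 and 0.15, and Klf2 and Lef1 fell by 0.24 and 0.10. For T cell migration receptors, 2 of 16 were higher and 7 lower (camera adjusted p = 0.248), where Cxcr4 and Cxcr6 rose by 0.70 and 0.27, and Itgb1 fell by 0.56. Of 16 T cell identity genes, 1 was higher and 7 lower (camera adjusted p = 0.188); Cd3g rose by 0.16, and Zap70, Cd27 (which overlaps Vamp1), Lck and Cd5 fell by 0.43, 0.43, 0.28 and 0.26. The medians of the T cell identity, migration, p53, TH2 and non-pathogenic TH17 lists were below 0 and turned above 0 with scaling to library totals. The counts moved too. With library totals 4 T cell identity genes were higher and 5 lower, 5 and 5 migration receptors, and 7 and 2 quiescence genes. For p53 targets the counts were then 6 and 5, for lysosome genes 14 and 4, and for NRF2 and antioxidant genes 11 and 8. Median, mean and test differed in sign for the regulatory, non-pathogenic TH17, TH1, NRF2, heat shock and B cell lists.

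Most markers of other cell types were weak or not tested. Ighm and Pecam1 were not weak, at 86.9 ± 3.11 and 78.6 ± 3.12 CPM in control and 77.8 ± 6.20 and 82.1 ± 9.56 CPM in NorUDCA libraries. Of 6 CD8 T and NK cell markers tested, 3 were lower and 0 higher (camera adjusted p = 0.634), with Klrk1 1.71-fold lower from 2.66 ± 0.240 CPM, Nkg7 1.75-fold lower and Klra7 1.86-fold lower; Nkg7 and Klra7 did not pass with DESeq2 (adjusted p = 0.0673 and 0.0676), nor Klra7 without control library 1 (0.0771), control library 3 (0.0535), NorUDCA library 2 (0.0719) or NorUDCA library 4 (0.0731). Of 5 B cell markers, 2 were higher and 1 lower (camera adjusted p = 0.680): Cd79a and Fcmr rose to 2.87 ± 0.656 and 4.48 ± 0.523 CPM, and Ighm fell by 0.16 on the log2 scale, a call lost with library totals (adjusted p = 0.222). Without NorUDCA library 1, Ighm stood at -0.10. The γδ T cell, myeloid, erythroid and platelet, and stromal lists had 1, 3, 1 and 2 tested members. Of these Trdc (which overlaps Trdv5 and Gm43434), Zbtb46 and Itga2b rose by 0.68, 1.08 and 0.82 on the log2 scale, to 3.23 ± 0.510, 0.947 ± 0.133 and 2.52 ± 0.245 CPM. The stromal markers Col1a1 and Pecam1 did not pass; without NorUDCA library 3 Pecam1 did (log2 fold change 0.14, adjusted p = 0.00451).

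Over the 30 lists tested, camera called 12, with 4 up and 8 down. With an estimated correlation 2 held, glycolysis and hypoxia, and by fry, which asks only whether the genes of a list move on balance in 1 direction, 25 did. NorUDCA libraries had more detected genes, at 23080 ± 260 against 22381 ± 69.4 (exact permutation p = 0.0286), and the share of ribosomal RNA counts was 0.374 ± 0.0456% against 0.395 ± 0.0698% (exact permutation p = 0.629).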

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

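For each group of 4 libraries, the gap between the most distant library and its nearest neighbour was divided by the range of the group. In 17 of 315 groups of values (5.40%) this share passed the limit that chance passes in about 5% of groups, so the number of such groups is near that of chance, and no explanation was tested for them.

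Among NorUDCA libraries, library 3 stood apart for 4 genes. Its Abca1 level was 14.4 CPM against 19.0 to 19.5 CPM in the others (share 0.904). Its Cd27 level was 24.1 CPM against 28.8 to 29.2 CPM (share 0.921). For Il17f it held 909 CPM against 1033 to 1052 CPM (share 0.869), and for Pgd 120.0 CPM against 107 to 108 CPM (share 0.893). NorUDCA library 1 stood apart for another 4 genes. Its Ifit1 level was 10.7 CPM against 4.52 to 5.14 CPM (share 0.900), and its Nr4a2 level 35.9 CPM against 26.9 to 27.3 CPM (share 0.964). For Plaur it held 11.4 CPM against 8.32 to 8.61 CPM (share 0.906), and for Smim3 126 CPM against 102 to 106 CPM (share 0.832). NorUDCA library 4 had 0.994 CPM of Fzd7 against 1.69 to 1.80 CPM (share 0.863) and 31.1 CPM of Neu1 against 29.6 to 29.7 CPM (share 0.913). NorUDCA library 2 alone had a count of Nr1h4, 1 in all, at 0.0439 CPM (share 1).

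Among control libraries, library 1 had 4.37 CPM of Ccl3 against 3.61 to 3.74 CPM (share 0.832) and 0.637 CPM of Zbtb46 against 0.356 to 0.401 CPM (share 0.840). Control library 3 had 8.94 CPM of Id3 against 10.0 to 10.2 CPM (share 0.872), and 200 CPM of Slc2a3 against 237 to 241 CPM (share 0.917). Control library 4 had 1117 CPM of mt-Nd2 against 1177 to 1187 CPM (share 0.857). Control library 2 alone had counts of Gpbar1, 2 in all, at 0.0850 CPM (share 1).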

How the results depend on the processing

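The counts with a mean of at least 5 CPM, the fit without NorUDCA libraries 1 and 3 and the removal of ribosomal RNA genes were chosen after the data were seen. The count of changed genes (8896) stayed within 1.5 times its value in each alternative except replicates 3 and 4 alone, with 5573 genes (2723 higher, 2850 lower), where fewer libraries were fitted. It was 8129 with DESeq2, 8806 with the replicate block, 8698 without NorUDCA libraries 1 and 3, and 8309 to 9302 when 1 library was left out. No pairing by replicate number was detected, as correlations of residuals between equal numbers ran from -0.08 to 0.17. This does not exclude that equal numbers shared a mouse or culture. The count of genes changed at least 2-fold (747) depended on weakly expressed genes and on the pseudocount. It was 1303 without a low-count filter (937 higher, 366 lower), where more genes were tested, and 343 genes were higher with a CPM of at least 1 in at least 4 libraries. With a mean of at least 5 CPM it was 234 (140 higher, 94 lower). On FPKM with a pseudocount of 1 it was 182 (93 higher, 89 lower), or 184 (93 and 91) without a filter, and with a pseudocount of 0.1 it was 343 (200 and 143). Of the 12 list calls, 2 held with an estimated correlation, and fry gave 25. The adjusted p with an estimated correlation was 0.523 for the TH17 lineage, T cell receptor, ATF4, ER unfolded protein, nuclear-encoded and mitochondrially encoded oxidative phosphorylation and interferon lists, 0.686 for cholesterol synthesis, 0.716 for the cell cycle and 0.352 for ribosome biogenesis. For the TH17 lineage list, the adjusted p ran from 0.00868 to 0.0742 when 1 library was left out, the highest without NorUDCA library 3, and it was 0.0584 without NorUDCA libraries 1 and 3; the cause was not tested. Over the named genes that are reported, 3948 of 4024 comparisons with an alternative kept their direction and their side of the threshold, 61 lost the call, 2 gained one and 13 changed direction, none of which passed in either fit. With library totals, Il17a stood at a log2 fold change of 0.0631, Il17f at 0.0197, Tbx21 at 0.0355 and Vdr at 0.00428. With upper-quartile scaling, Il17a stood at 0.0322 and Tbx21 at 0.00293. Il17a stood at 0.0176 with replicates 1 and 2 alone, at 0.0391 without NorUDCA libraries 1 and 3, and from -0.0615 to 0.0346 when 1 library was left out. Tbx21 stood at 0.164 with replicates 3 and 4 alone and from -0.283 to 0.124 when 1 library was left out. The TH1 list changed direction with fry (adjusted p = 0.817), with the replicate block (0.942) and without some single libraries (0.724 to 0.998 over all 8). The difference in mean library size, NorUDCA minus control, was -873132 for totals and 462040 for totals multiplied by the TMM factor (exact permutation p = 0.371). Il12rb2 lost its call most often. At 4 libraries per group and this depth, 52% of simulated 1.2-fold changes were found, but with 200 genes changed by fixed factors. With 8896 calls in the data the adjusted threshold was less strict, so this share does not measure what was missed here. Genes not called may still differ by small factors.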

Other observations

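Chosen after the results were seen were the gene lists of aryl hydrocarbon receptor targets, tRNA synthetases, ribosomal proteins and hepatocyte or epithelial markers, and the tests of liver or epithelial markers, of the aryl hydrocarbon receptor, of the Hif1a transcript and of genomic DNA; the count of splits with an estimated correlation was added after that with the preset correlation was seen.

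Target genes of the aryl hydrocarbon receptor (AHR), a sensor of foreign and metabolic compounds, were higher with NorUDCA. Of 9 members tested 7 rose and 0 fell, with a median log2 fold change of 1.94 (camera adjusted p = 2.12e-14; adjusted p = 0.0243 with an estimated correlation). For this and the other lists added after the data were seen, camera p-values were adjusted over those lists alone. They are therefore not on the same footing as those of the 30 planned lists. The AHR list is not independent evidence, since Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1 and Nfe2l2 had been seen when it was written. Cyp1b1 rose 3.83-fold to 85.1 ± 10.4 CPM, and Tiparp from 47.8 ± 2.43 to 197 ± 24.3 CPM. Cytosolic aminoacyl-tRNA synthetase genes split, with 11 of 20 higher and 9 lower (camera adjusted p = 0.233). Cars1 and Aars1 rose by 1.02 and 0.90 on the log2 scale, and Farsa fell by 0.51.

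Cytosolic ribosomal protein genes differed little: 9 of 31 were lower and 0 higher (5 and 0 adjusted over the list alone; 3 lower and 4 higher with library totals), with a median of -0.04 that turned to 0.04 with library totals (camera adjusted p = 0.233). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 rose, by 0.73 (SE 0.05, edgeR adjusted p = 7.54e-09) and 0.33 (SE 0.05, edgeR adjusted p = 2.27e-05) on the log2 scale, while 11 of 12 mitochondrial messenger RNAs were lower. Of 12 hepatocyte and epithelial markers, 3 were tested; Epcam rose to 3.05 ± 0.160 CPM and Cldn4 to 0.785 ± 0.209 CPM, and Alb had 0 counts.

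Cyp1a1, Cyp1b1, Ahrr and Tiparp rose together. The rise did not depend on which scaling was used: the lowest log2 fold change of the 4 over 3 other scalings was 1.94 (Cyp1b1). These scalings moved log2 fold changes by a median of at most 0.083, too little to remove such a rise. They could therefore not test scaling as a cause. Liver or epithelial cells were argued against, since their 12 markers summed to 5.21 CPM in NorUDCA libraries against 227 ± 44.2 CPM of Cyp1a1. Activation of the AHR may underlie the rise but stays open: of Scin, Xdh and Ugt1a7c, put on the list before their values were looked up, 1 rose, Scin, by 3.00 on the log2 scale. Xdh stood at -0.06 (edgeR adjusted p = 0.590) and Ugt1a7c at -0.28 (SE 0.35, edgeR adjusted p = 0.516). Ugt1a7c was weak, at 0.481 ± 0.185 CPM in control and 0.392 ± 0.134 CPM in NorUDCA libraries, so it tells little. Scin was weak too, at 0.230 ± 0.0713 CPM in control and 1.87 ± 0.601 CPM in NorUDCA libraries, and weakly expressed genes rose as a class. The Ahr transcript itself fell by 0.53 on the log2 scale. Whether NorUDCA, a contaminant of it or a vehicle would be the source was not tested.

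Hypoxia and glycolysis genes fell together. A lower level of the Hif1a transcript was argued against, since the lower 95% bound of its log2 fold change was -0.0787. The fall did not depend on which scaling was used: the median of the hypoxia list was at most -0.91 over 3 other scalings. These scalings moved log2 fold changes by a median of at most 0.083, too little to remove the fall. They could therefore not test scaling as a cause. Lower HIF1A protein or activity could give this pattern, and stays open because no protein was measured.

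Weakly expressed genes were higher with NorUDCA: the 6567 genes with a mean of at most 0.5 counts summed to 58.3 ± 2.03 CPM in control and 76.3 ± 9.58 CPM in NorUDCA libraries (exact permutation p = 0.0286). Depth was argued against, since after thinning to equal totals the lowest NorUDCA library still detected 548 more genes than the highest control library. The ratio of the summed levels, NorUDCA over control, was 1.31, and 1.23 without NorUDCA library 1. Over 3 other scalings, with all libraries, it was at least 1.31. These scalings differed too little to remove the rise, so they could not test scaling as a cause. Carryover of genomic DNA stays open: 1552 olfactory and vomeronasal receptor genes stood at 34.0 ± 3.10 and 36.0 ± 3.18 CPM (exact permutation p = 0.343), a spread too wide to decide. The 1506 of them with a mean of at most 0.5 counts held 10 to 23 counts per control and 13 to 26 per NorUDCA library, a level 1.22 times that of control (exact permutation p = 0.429), too few to decide either. Less complete silencing or slower decay of such transcripts may be at work and was not tested.

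Of the 35 splits of the 8 libraries into 4 and 4, the real one gave 8896 changed genes and 747 changed at least 2-fold. The highest other count was 0 for both, so 1 of 35 gave as many, the smallest share possible. Each other split mixed treated and untreated libraries, which puts the difference between the groups into its residuals. A count of 0 there does not measure how often chance gives calls, so chance was not excluded by it. For the 12 lists called with the preset correlation, 8 splits gave as many, up to 14. Each of these but the real one kept 3 libraries of a treatment together, and so part of the difference between the groups. Their number therefore does not measure how often chance gives list calls. A split with 2 libraries of each treatment on each side still gave 11, and chance was not excluded. With an estimated correlation, 1 of 35 splits gave as many as the 2 real calls (highest other 0), with the same limit as for the gene counts.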
